A study of Drosophila melanogaster with 12 samples.

How the data were processed

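Gene expression was measured on 12 Affymetrix Drosophila_2 arrays, hybridised with RNA from L3 larvae of Drosophila melanogaster. Per the labels, the arrays fall into 4 groups of 3: wing discs carrying the nub-Gal4 driver alone, wing discs carrying nub-Gal4 with a UAS transgene for the transcription factor MiT, and hindgut with Malpighian tubules from wild-type larvae or from MiT mutants. The group and replicate number of each array were taken from its title. The labels do not say that the replicates came from separate cultures or batches of animals, so the p-values measure only the spread between these samples.

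The deposited expression values are on the log2 scale, and the submitters' processing notes name GCRMA, which subtracts background and normalizes between arrays; no version is given in the sources used here. The per-sample values and the series table held the same numbers, with a largest difference of 0. The authors deposited a table of an analysis of variance as well, with p-values, p-values adjusted by a step-up procedure and signed fold changes for both comparisons, per the file headers; its fold for the wing discs runs from the overexpressing to the control discs, opposite to the direction used here. The adjusted p-values of that table entered 1 alternative setting and nothing else.

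The arrays hold 18952 probe sets, of which 183 Affymetrix controls were left out. Probe sets were named through the RefSeq accessions and symbols in the files and a RefSeq gene table of assembly Release 6, which was used for names and gene order only, since the files name no genome build. In all, 14366 probe sets had 1 gene (13812 by accession, 358 by symbol, 196 under the name in the file alone), 418 had several and 3985 had none. A probe set with several genes names none in the text, and 2 names in the lists, Tor and Dl, had no match. Probe sets with a log2 value of at least 4 on at least 3 arrays were tested, which left 8678 probe sets and 7809 named genes. A gene with several probe sets was represented by the one with the highest mean; of 374 genes with several tested probe sets, 0 had calls in opposite directions in the wing discs and 4 had in the hindgut-tubule samples. Where the mean of 1 group lies under a log2 value of 4, a change is given as at least N-fold, computed against that level, since lower values are not told apart from background here.

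Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 12 arrays in 1 fit, trend and robust options off), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene below is limma's. The fit has 8 residual degrees of freedom and 2.08 prior ones, and it shares 1 variance per probe set between both tissues. That matters here, because the mean SD of a probe set over replicates was 0.34 and 0.37 in the wild-type and mutant hindgut-tubule groups and 0.18 and 0.15 in the control and labelled overexpressing discs. A fit to the 6 arrays of each tissue alone was therefore listed beforehand as an alternative.

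The procedure was tested on simulated data built from the real means. With 1500 changed probe sets among 8826 tested and the spread of each tissue kept, the 12-array fit recovered 46.2% of log2 changes of 0.5, 80.8% of 1 and 93.2% of 2 in the wing discs, and 2.76% of its calls were false. In the hindgut-tubule samples it recovered 51.0%, 75.5% and 93.7%, but 18.4% of its calls were false; with 200 changed probe sets among 8830 tested that share was 49.6%. The fit to the 6 hindgut-tubule arrays kept false calls at 3.85% with 1500 changed probe sets and recovered 28.0%, 60.9% and 87.7%. With equal spread in both tissues, 8904 probe sets tested and 1500 changed, false calls of the 12-array fit made up 4.88% in the wing discs and 4.62% in the hindgut-tubule samples, and with 200 changed 1.77% and 12.4%. A hindgut-tubule call of the 12-array fit is accordingly less secure than a wing disc call.

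Gene lists were written before the data were examined, from general knowledge of fly genes: 7 main lists (the V1 and V0 sectors of the V-ATPase, lysosomal hydrolases and membrane proteins, autophagy, TORC1 and nutrient sensing, endolysosomal trafficking, and genes of chromosome 4, where the Mitf gene lies) and 21 further lists of metabolism, stress, signalling and tissue markers. A list was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 28 lists, and again with the correlation estimated from the data. The list of detoxification genes was filled by name and includes Cyp1, a cyclophilin. Shared calls between the comparisons were tested with a one-sided Fisher's exact test, beside the number that independent lists would share. The wing disc and hindgut-tubule comparisons use no array in common, but the main fit gives both the same variance per probe set. Their call lists are therefore not fully independent, as Fisher's test assumes. Fits to the arrays of each tissue alone do not share this variance.

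The genes named were fixed by rule: Mitf; the 10 largest rises and 10 largest falls past the test whose groups do not overlap; up to 10 members of each main list past the test, by adjusted p; the 4 members with the smallest p of any other list described; up to 15 genes of the overlap by the smaller of their 2 changes, and its V-ATPase members; and 3 markers per list for the tissue check. Genes named outside this rule are said to have been chosen after their values were seen.

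The replicate numbers were checked for pairing through the correlation, over probe sets, of each array's deviation from its group mean. In the hindgut-tubule samples same-numbered wild-type and mutant arrays correlated at 0.29, 0.38 and 0.14, so the numbers pair these samples by the rule set beforehand. Differently numbered arrays correlated at -0.39 to 0.34, and mutant array 3 with wild-type array 1, at 0.34, lay above the 0.29 and 0.14. The pairing is therefore only weakly shown. The fit with the number as a block is given where it changes a call. The alternatives tried were no filter, a filter at a log2 value of 6, trend and robust options, the 6 arrays of each tissue alone, the replicate block, renewed quantile normalization within each tissue, centring on array medians, a threshold of at least 2-fold, the mean of all probe sets of a gene, the authors' adjusted p, and leaving out each array in turn. Leaving out the number 2 arrays of both hindgut-tubule groups was added after seeing the data. Array signal was alike apart from mutant hindgut-tubule array 2. On the other arrays 41.3% to 42.1% of probe sets reached a log2 value of 4, and on that array 44.7%. Its median over all probe sets except controls was 3.03, against 2.64 to 2.71 on the others. Its mean correlation with its own group was the lowest of all arrays (0.952). The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.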

Results

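Transcript levels were compared on 12 arrays from Drosophila melanogaster larvae, in 4 groups of 3. The wing imaginal disc is the larval epithelium that forms the adult wing, and nub-Gal4 drives a UAS transgene in its wing-forming region. Hindgut and Malpighian tubules, the excretory organs of the fly, were collected together and are called hindgut-tubule samples here. MiT is the fly member of the MITF/TFE family of transcription factors and appears in the files as Mitf. The series asked which loci are raised by gain of MiT in the wing disc and lowered by its loss in the hindgut and tubules.

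Markers of the tissues were compared first. All 30 measured genes of a wing disc patterning list were higher in control discs than in wild-type hindgut-tubule samples, among them ara, vg and ap, and 19 of 21 measured Malpighian tubule markers were higher in the hindgut-tubule samples, among them Uro, Irk2 and salt. Of 11 hindgut markers, 5 were higher in the hindgut-tubule samples, among them cad, fkh and Abd-B, and 5 in the discs. Correlations between replicate arrays were 0.982 to 0.990 in the labelled overexpressing discs and 0.943 to 0.986 in the mutant hindgut-tubule samples.

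Mitf itself was 4.51-fold lower in the mutant hindgut-tubule samples than in wild type (log2 4.41 ± 0.20 against 6.59 ± 0.44, SD, n = 3 each; limma adjusted p = 5.87e-05). In the wing discs the same probe set read 8.11 ± 0.10 in the samples labelled as overexpressing MiT and 7.996 ± 0.13 in control discs (SD, n = 3 each), a log2 difference of 0.12 with an SE of 0.20 and a limma adjusted p of 0.824. The array therefore showed no rise of Mitf in those discs. Whether the probe set lies in sequence that the transgene carries is not given in the sources used here, so this value does not check the label, and the samples are called discs labelled as overexpressing MiT throughout.

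**Figure D1:**
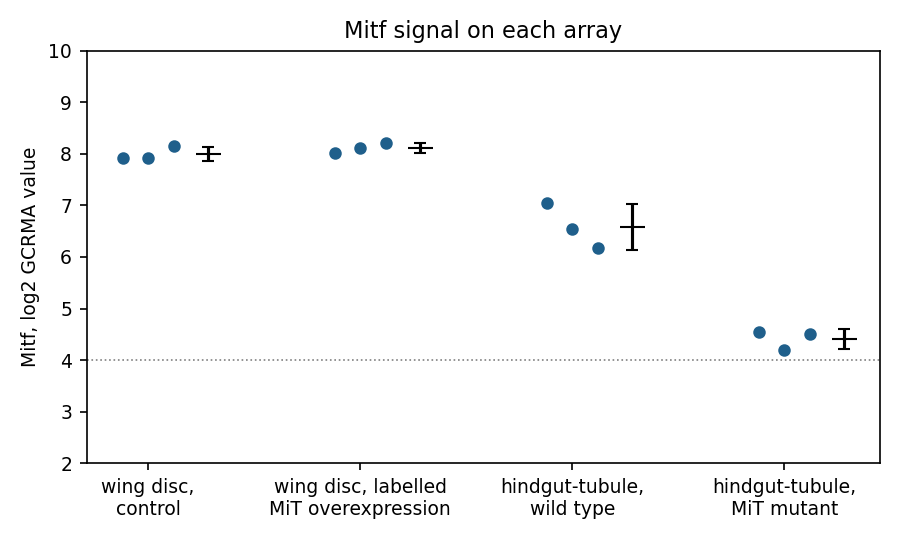
Log2 GCRMA value of the Mitf probe set on each of the 12 arrays (points), with the mean and SD of each group beside them; the dotted line marks the level of 4 used as the filter. The mutant hindgut-tubule arrays have a mean of 4.41 against 6.59 in wild type, and the 2 wing disc groups have means of 8.11 and 7.996.

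The first comparison asked what changed in wing discs with the MiT transgene. The V-ATPase is the proton pump that acidifies lysosomes and other compartments. In the discs labelled as overexpressing MiT, 14 of its 20 subunits over the filter on dim probe sets were higher and 0 lower. The median over these 20 was 1.59-fold (log2 0.67, against 0.34 over all 33 without the filter). Ilp8, a relaxin-like peptide that discs release when their growth is disturbed, rose at least 20.0-fold, and 5 of 9 hemocyte markers and 3 of 12 muscle markers were higher. Of 30 genes that pattern the wing 6 were lower, among them kn (knot), a transcription factor of the central wing, which fell by 3.35 on the log2 scale. The V-ATPase, hemocyte, muscle and patterning lists all passed camera at its preset correlation, and none of them with an estimated one. In all, 619 probe sets were higher and 457 lower of 8678 tested (limma), and 343 and 165 of them differed at least 2-fold. The 2 groups did not overlap for 47.8% of the probe sets, against 10% by chance.

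Genes are named here by the rank of their fitted log2 change. Among the rises, CG9757 went from a log2 level of 5.93 ± 0.61 to 12.40 ± 0.55 (SD, n = 3 each), a log2 change of 6.47 with an SE of 0.41 (adjusted p = 6.39e-06). CG13046 rose by 6.27, CG7296 by 5.64, CG31098 by 4.98 and Antdh, an antennal dehydrogenase, by 4.62 on the log2 scale. Lower bounds alone are given for genes whose control discs lay under a log2 level of 4: CG4757 (at least 42.7-fold), Obp50e, an odorant-binding protein (at least 26.9-fold), Ilp8 (at least 20.0-fold), CG8563 (at least 18.9-fold) and CG6409 (at least 18.6-fold). The falls included CG14406 (at least 19.2-fold), Rala, a small GTPase (a log2 change of -3.79, SE 0.16, adjusted p = 2.92e-07), nab, a transcriptional cofactor used in the wing (at least 5.01-fold), Achl (at least 4.26-fold) and spok (spookier), an enzyme of ecdysone synthesis (-4.21). Eip78C, CG9822, yellow-c, Ugt301D1 and b (black) completed the 10, with CG9822 nearest the threshold (adjusted p = 0.0463). Ranked by the folds and bounds as printed, 9 of the 10 rises and 8 of the 10 falls stayed, and kn (10.2-fold) came before nab and Achl. The fit to the 6 wing disc arrays called all 10 rises and 9 of the 10 falls, without CG9822. Of these 20 genes Eip78C, CG9822 and b lost the call in 4 of the 6 fits that left out 1 disc array, with adjusted p up to 0.115, 0.143 and 0.0996.

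Of 20 measured V-ATPase subunits, 14 were higher in the discs labelled as overexpressing MiT, 0 were lower and 6 did not pass the test. In the cytosolic V1 sector 7 of 10 were higher (9 when adjusted over the list alone), with a median log2 change of 0.71, for example Vha26 (1.00, SE 0.10, adjusted p = 0.000131), Vha14-1 (0.95, adjusted p = 0.000458) and Vha68-2 (0.95, adjusted p = 0.000547). In the membrane V0 sector 7 of 10 were higher (8 adjusted over the list alone), with a median of 0.62, for example Vha100-2 (1.23, SE 0.17, adjusted p = 0.00115) and the accessory subunits ATP6AP2 (0.91) and VhaAC45 (0.79). Camera gave adjusted p = 1.62e-07 for V1 and 1.27e-06 for V0, against adjusted p = 0.42 and adjusted p = 0.237 with an estimated correlation. All 14 calls were also made in the fit to the 6 wing disc arrays, and Vha44 alone lost its call without single arrays, namely control disc 1 or labelled disc 3 (adjusted p up to 0.0622).

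The other lists around the lysosome did not pass camera in the discs. Of 22 measured lysosomal hydrolases and membrane proteins, 2 rose (CtsL1, the cysteine protease cathepsin L, by 0.97, and Hexo2) and 2 fell (Cln3 by 2.20 on the log2 scale, and Cln7), with a median of 0.05 (camera adjusted p = 0.676); adjusted over the list alone, 2 rose and 3 fell. Of 25 autophagy genes 0 passed the limma test, also adjusted over the list alone (median -0.03, camera adjusted p = 0.942), and 1 was higher at an unadjusted p under 0.05. The 6-array fit called 3 autophagy genes higher and 1 lower. Of 24 genes of TORC1 and nutrient sensing, Thor, the translational repressor 4E-BP, rose by 1.51 (adjusted p = 0.00831) and REPTOR, a transcription factor restrained by TORC1, by 0.90, while Sesn fell by 1.19 on the log2 scale, with a camera adjusted p of 0.308 for the list and the same counts adjusted over the list alone. Of 40 endolysosomal trafficking genes, Ccz1 and Vps29 fell and 38 did not pass the test, and 0 passed adjusted over the list alone. The trafficking list had a median of -0.11 with 28 of 40 negative and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.163). Its mean on the labelled discs, -0.17, -0.11 and -0.088 minus the control mean, lay under that on every control disc (-0.038 to 0.029). Chromosome 4 had 1 gene higher (anne) and 1 lower (Arf4) of 54 (camera adjusted p = 0.161), against 0 and 1 adjusted over the list alone. Cln7, REPTOR, Ccz1, Vps29 and anne lost the call in each of the 6 fits without 1 disc array, Sesn in 5 and Hexo2 in 4, with adjusted p up to 0.161.

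Among the 21 further lists, 5 passed camera in the wing discs. Hemocyte markers had a median log2 change of 1.58, with 5 of 9 higher and 0 lower (the same adjusted over the list alone), among them Hml (2.64, SE 0.32, adjusted p = 0.000443), He (2.29), eater, a phagocytic receptor (2.10), and Pxn (1.58). Muscle markers had a median of 0.61, with 3 of 12 higher over all genes and 11 adjusted over the list alone, among them Mlc2, a myosin light chain (1.495, adjusted p = 0.0142, and up to 0.0651 without control disc 3 or labelled disc 2). Without either of these discs 0 of the 12 passed. Detoxification enzymes had 18 members higher and 2 lower of 104 (22 and 2 adjusted over the list alone), among them Ugt35A1 (at least 4.50-fold), Cyp6a23 (at least 3.54-fold) and Cyp6a17 (2.22), although the list's median was 0.05. Of 11 genes of cell death and JNK signalling 4 were higher (5 adjusted over the list alone): Ilp8, the cytokine upd1 (1.93, adjusted p = 0.000406), Socs36E, a target of the cytokine pathway (1.18), and Xrp1, a stress-response transcription factor (0.88, adjusted p = 0.000458). The list's median was 0.02, and its call ended without labelled disc 1, 2 or 3 (adjusted p = 0.126, 0.264 and 0.176), in the 6-array fit (0.104), with the replicate block (0.0926) and without the number 2 arrays of both hindgut-tubule groups (0.0666). Without labelled disc 1, 2 or 3, 10 rather than 11 members passed the filter and 3 were higher. The filter needs 3 arrays, so a gene over its level on the labelled discs alone drops out of such a fit. These 3 fits therefore do not test whether the list rests on single discs. Wing disc patterning genes had a median of -0.29, with 6 of 30 lower and 0 higher (7 and 1 adjusted over the list alone), among them kn (SE 0.11, adjusted p = 3.06e-08), al (-1.84), vg, the wing selector gene (-0.89, adjusted p = 0.00182), and sc (-0.60). Camera adjusted p was 0.000217 for hemocyte, 0.000134 for muscle, 0.000257 for detoxification, 0.0145 for cell death and 0.00761 for patterning, and with an estimated correlation adjusted p was 0.449, 0.838, 0.449, 0.42 and 0.879. Fat body markers, a tissue outside the disc, varied between the arrays in the same samples: their mean minus the control mean was 0.52, -2.72 and -5.27 on the 3 labelled arrays, and 0 of 8 passed the limma test, with 3 lower at an unadjusted p under 0.05. The other 16 lists did not pass camera (adjusted p from 0.0775 to 0.942). Of these the fat body list passed as lower without labelled disc 1 (2.36e-05), without control disc 2 (0.0271) and without the filter on dim probe sets (0.0326). The ribosomal list passed without control disc 1 (0.0393), labelled disc 3 (0.0418) or the filter (0.00237). The list of ecdysone response and staging, at 0.0832, passed in 6 settings, among them the 6-array fit (0.0146) and the replicate block (0.0301). With an estimated correlation adjusted p was 0.963 for each of these 3 lists.

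The wing disc counts changed with the fit and with single arrays. The fit to the 6 wing disc arrays called 1209 higher and 1395 lower, which include 601 and 440 of the calls above. The higher count came to 383 without labelled overexpressing disc 2 and 378 without disc 3, and the lower count to between 216 and 290 without any 1 of the 6 arrays.

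The second comparison asked what changed in the hindgut and tubules of MiT mutants. V-ATPase subunits were mostly lower in the mutant, with 17 of the same 20 lower and 1 higher. Their median fall was 3.28-fold (log2 -1.72, against -0.56 over all 33). Oxidative phosphorylation genes had a median log2 change of -0.60, and 17 of 37 passed as lower, of which the 6-array fit called 0 and the replicate block 17. Neither the V-ATPase lists nor that list passed camera with an estimated correlation. Cyp12d1-d, a cytochrome P450, fell at least 606-fold and CG15201 at least 200.5-fold, and Lcp9, a larval cuticle protein, rose at least 199.9-fold. In all, 702 probe sets were higher and 626 lower of 8678 tested (limma), of which 270 and 253 differed at least 2-fold. The 2 groups did not overlap for 26.04% of the probe sets, against 10% by chance.

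Cyp12d1-d had a log2 level of 13.24 ± 0.33 in wild type and 3.93 ± 0.69 in the mutant (SD, n = 3 each; adjusted p = 2.25e-08). The titles name the mutant samples EMSTZ2, but the labels do not give the background strain of either genotype, so these changes are between the samples as labelled. Further falls, named by the rank of the fitted log2 change, were those of CG15201, the antimicrobial peptide gene AttD (at least 35.7-fold), Npc2f, of the NPC2 family of sterol-binding proteins (at least 24.9-fold), CG8160 (at least 22.1-fold), BaraA2 (at least 21.1-fold), CG18180 (at least 15.5-fold), CG9514 (at least 10.4-fold), Prx6c, a peroxiredoxin (a log2 change of -4.76, SE 0.53), and Rh50, an ammonium transporter (-4.58, SE 0.57). The rises named after Lcp9 were CG7191 (at least 65.6-fold, adjusted p = 9.43e-10), CG8768 (at least 30.9-fold), CG14879 (at least 28.8-fold), CG13806 (at least 28.6-fold), CG11893 (at least 27.4-fold), Jhedup, a juvenile hormone esterase relative (at least 14.0-fold), CG11149 (at least 12.9-fold), mthl8 (at least 8.59-fold) and ppk12, a sodium channel subunit (at least 7.62-fold). In wild type each of these rising genes lay under a log2 level of 4. Ranked by the folds and bounds as printed, 6 of the 10 rises and 8 of the 10 falls stayed, and path (17.9-fold) came before Jhedup, CG11149, mthl8 and ppk12. The fit to the 6 hindgut-tubule arrays called all 10 rises and 9 of the 10 falls, without BaraA2.

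Both sectors of the V-ATPase were lower in the mutant. In the V1 sector 9 of 10 were lower and Vha68-1 was higher, with a median log2 change of -1.80, for example Vha44 (-2.19, SE 0.14, adjusted p = 3.68e-06), Vha13 (-1.98, adjusted p = 2.56e-06) and VhaSFD (-1.72, adjusted p = 1.58e-06). Vha68-1 rose by 0.97 (SE 0.15, adjusted p = 0.00186), while Vha68-2, the other catalytic subunit A gene measured, fell by 1.91 on the log2 scale. In the V0 sector 8 of 10 were lower and 0 higher, with a median of -1.46, for example VhaAC39-1 (-2.09, adjusted p = 1.07e-06), Vha100-2 (-2.05) and Vha16-1 (-1.04, adjusted p = 6.80e-05). Counts adjusted over the list alone were the same. Camera adjusted p was 8.52e-12 for V1 and 1.65e-10 for V0, against adjusted p = 0.249 and adjusted p = 0.067 with an estimated correlation. The fit to the 6 hindgut-tubule arrays made 16 of these 18 calls, without Vha36-3 and Vha100-5, and the replicate block ended the call of Vha100-5 (adjusted p = 0.0737). Without single arrays Vha36-3 lost its call in 6 of 6 fits and Vha100-5 in 4 (adjusted p up to 0.0883 and 0.0798). Malpighian tubule markers in the same samples had a median log2 change of 0.06, with 2 of 21 higher and 1 lower.

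**Figure D2:**
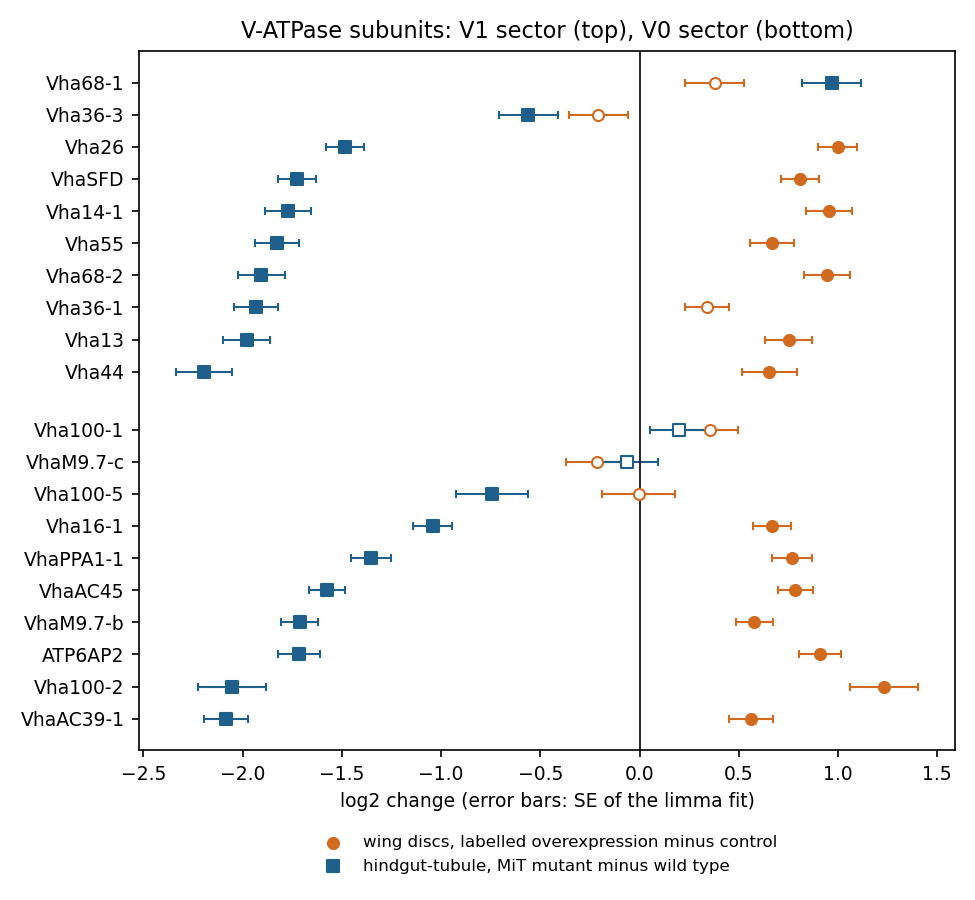
Log2 change of each of the 20 measured V-ATPase subunits in the wing discs (circles) and the hindgut-tubule samples (squares), with the SE of the limma fit; filled symbols passed the test and open ones did not. The medians over all 20 are 0.67 in the discs and -1.72 in the mutant, and Vha68-1 lies apart at 0.97 in the mutant.

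The remaining lysosomal lists did not follow the V-ATPase in the mutant. Of 22 lysosomal genes 2 were higher, Ppt1, a lysosomal thioesterase (0.64, adjusted p = 0.00381), and Hexo1, and 0 lower, also adjusted over the list alone. The 6-array fit called neither of them. The list's camera adjusted p was 0.0637, 0.0128 with the replicate block, 0.0131 without mutant array 2 and 0.958 with an estimated correlation. Hexo1 lost its call without wild-type array 3, mutant array 1 or mutant array 3 (adjusted p up to 0.0799). Of 25 autophagy genes Atg12 rose (0.51, adjusted p = 0.00478) and 24 did not pass the test, also adjusted over the list alone, and the 6-array fit did not call Atg12 (adjusted p = 0.0906). Among 24 genes of TORC1 and nutrient sensing, path (pathetic), an amino acid transporter, rose by 4.16 (SE 0.20, adjusted p = 6.54e-07) and Lst8 by 0.50, while REPTOR fell by 1.02 on the log2 scale and BHD by 0.45. Of these path alone was also called by the 6-array fit, and the replicate block ended the call of Lst8 (adjusted p = 0.0571). Without single arrays Lst8 lost its call in 3 fits and BHD in the fit without mutant array 3 (adjusted p up to 0.0927 and 0.0775). Of 40 endolysosomal trafficking genes Arl8, a GTPase that moves lysosomes, fell by 0.67 on the log2 scale (adjusted p = 0.00681, and 0.0966 in the 6-array fit) and 39 did not pass. The counts of both lists were the same adjusted over the list alone. Camera adjusted p was 0.765 for autophagy, 0.686 for TORC1 and 0.826 for trafficking.

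Genes of chromosome 4, on which Mitf lies, were higher in the mutant, with 15 of 54 higher and 3 lower (19 and 4 adjusted over the list alone) and a median log2 change of 0.28 (camera adjusted p = 0.000164, and adjusted p = 0.794 with an estimated correlation). Over all settings the chromosome 4 median ran from 0.11 to 0.37. The other chromosome arms had medians between -0.016 and 0.024 in the main setting. The genes that rose include unc-13, a synaptic vesicle protein (3.49, SE 0.34, adjusted p = 9.63e-05), mav, a TGF-beta family ligand (0.74, adjusted p = 0.00434), and yellow-h (1.24); Rnf11 passed the test too, with both group means under a log2 level of 4. The 3 that fell were Mitf, ATPsynbeta and Dyrk3 (a log2 change of -1.26, adjusted p = 0.0215). Dyrk3 is the next of the tested genes after Mitf in the annotated order and was chosen after its value was seen. The 6-array fit made 3 of these 18 calls, without mav, yellow-h and ATPsynbeta among others, and ATPsynbeta lost its call without mutant array 3 (adjusted p = 0.0578).

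Of the 21 further lists, 5 passed camera in the hindgut-tubule samples. All 37 measured oxidative phosphorylation genes had negative changes, 17 passed the test (24 adjusted over the list alone), and the median was -0.60, for example ND-B17.2 (-1.05, SE 0.19, adjusted p = 0.00438), UQCR-14 (-0.85, adjusted p = 0.0107) and COX4 (-0.63, adjusted p = 0.0074). The 6-array fit called 0 of these 17 genes, while the 12-array fit with the replicate block called all 17 and 31 of the 37 in all. Between same-numbered arrays the list's mean differed by -0.51, -0.60 and -0.64, and the list passed camera in the 6-array fit (adjusted p = 1.28e-09) and with the block (3.01e-16). Detoxification genes went both ways, with 27 higher and 9 lower of 104 (34 and 11 adjusted over the list alone) and a median of 0.24, among them Cyp4p2 (at least 5.61-fold higher), Ugt302K1 (at least 4.38-fold higher) and GstD5 (at least 1.71-fold higher), beside the fall of Cyp12d1-d. The 6-array fit made 16 of these 36 calls. Muscle markers had 3 of 12 higher, also adjusted over the list alone, among them wupA, a troponin (0.68, adjusted p = 0.00516), with a median of 0.49. The 6-array fit made 0 of these 3 calls. Antimicrobial peptide and recognition genes had 1 of 8 lower, AttD (3 adjusted over the list alone), and a median of -1.31. Cytosolic ribosomal proteins had 0 of 77 past the limma test, also adjusted over the list alone, with 8 higher at an unadjusted p under 0.05 and a median of 0.08. Camera adjusted p was 1.46e-10 for oxidative phosphorylation, 0.00583 for detoxification, muscle and ribosomal proteins, and 0.0119 for the antimicrobial list. With an estimated correlation adjusted p was 0.873, 0.794, 0.958, 0.958 and 0.794 for oxidative phosphorylation, detoxification, muscle, ribosomal proteins and the antimicrobial list. Without mutant array 2, the muscle, detoxification and ribosomal lists no longer passed (adjusted p = 0.385, 0.407 and 0.269), and the muscle and detoxification medians came to 0.30 and 0.15. Without wild-type array 1 the muscle (0.0502) and detoxification (0.0904) lists, and without wild-type array 2 or 3 or mutant array 2 the antimicrobial list (0.0564, 0.107 and 0.0832), did not pass. The antimicrobial median came to -0.66 without wild-type array 3, where 7 rather than 8 members passed the filter, as without wild-type array 2. Without the filter on dim probe sets the detoxification median was -0.014 (adjusted p = 0.115), and with a filter at a log2 value of 6 the antimicrobial list did not pass (0.0568). Leaving out the number 2 arrays of both groups, a setting added after seeing the data, left only oxidative phosphorylation past camera among these 5 lists. The other 16 lists did not pass camera (adjusted p from 0.0641 to 0.976). Among them the cell cycle list passed as higher without wild-type array 2 (0.00107), mutant array 1 (0.00642) or the filter (0.0168), and heat shock proteins without mutant array 2 (0.00971), without the filter (0.0338) and after renewed quantile normalization (0.0461). Both also passed without the number 2 arrays of both groups (0.0236 and 0.0232). With an estimated correlation adjusted p was 0.873 for the cell cycle list and 0.958 for heat shock proteins.

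**Figure D3:**
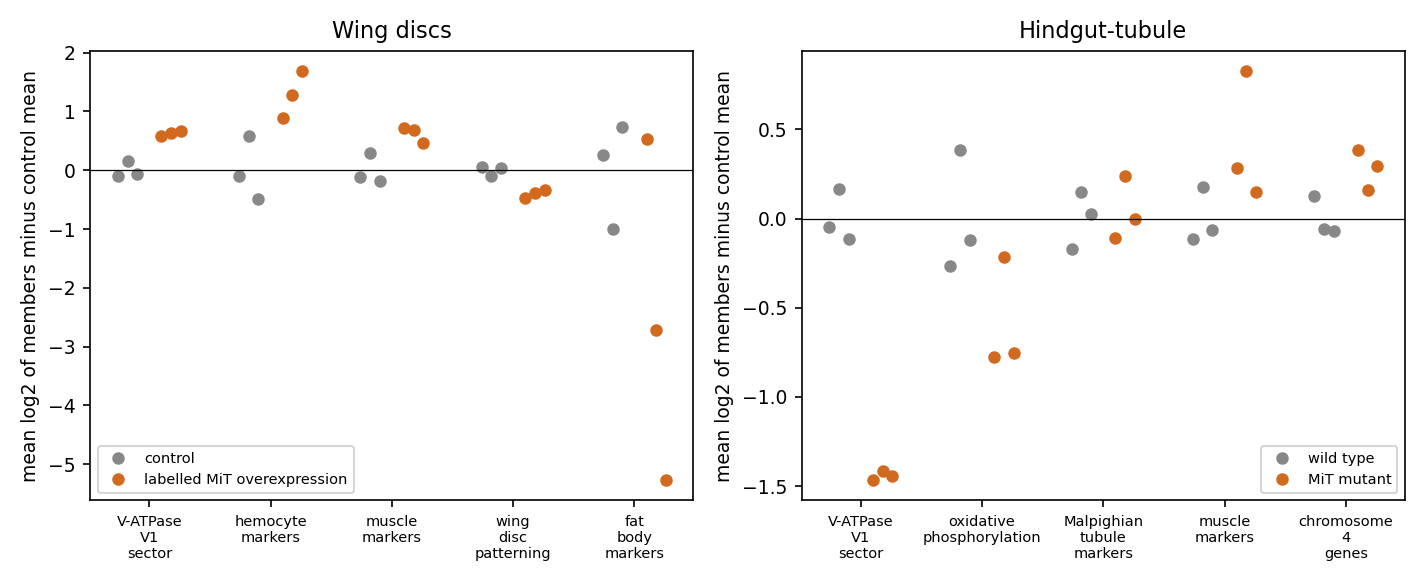
Mean log2 value over the measured members of 5 lists on each array, minus the mean of the control group, for the wing discs (left) and the hindgut-tubule samples (right). V1 sector subunits lie apart between groups on every array of both tissues, and fat body markers spread from 0.52 to -5.27 within the labelled overexpressing discs.

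The hindgut-tubule counts are the least secure, since the spread of these samples exceeds that of the wing discs with which they share a variance: the 6-array fit called 182 higher and 167 lower, which include 180 and 164 of the calls above. On simulated data with this spread, 18.4% of the hindgut-tubule calls of the 12-array fit were false with 1500 changed probe sets, and 49.6% with 200. The 6-array fit made 909 and 75 hindgut-tubule calls in these simulations. How many probe sets truly changed is not known, so neither share can be taken as that of the real calls. The higher count came to 460 without wild-type array 3, 433 without mutant array 3 and 1106 without mutant array 2, and 1288 higher and 984 lower without the number 2 arrays of both groups, a setting added after seeing the data.

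The third comparison joined the other 2, asking which genes were higher in the discs labelled as overexpressing MiT and lower in the mutant. Of the 60 genes that met both conditions 14 were V-ATPase subunits: Vha13, Vha14-1, Vha26, Vha44, Vha55, Vha68-2 and VhaSFD of V1, and Vha16-1, Vha100-2, VhaAC39-1, VhaAC45, VhaM9.7-b, VhaPPA1-1 and ATP6AP2 of V0. Among shared genes with every group mean over a log2 level of 4, the largest paired changes lay outside it, in CG31098 (4.98 in the discs and -3.98 in the mutant), CG3764 (3.35 and -3.45) and CG10211 (3.17 and -1.67). Further members were Sirup (1.65 and -1.70), CG9757 (6.47 and -1.52), mol (1.32 and -1.68), GstT4 (1.88 and -1.26), CG11050 (1.16 and -1.39), CG8272 (1.14 and -1.20) and CG3961 (1.499 and -1.11). CG13046 rose by 6.27 in the discs and fell at least 2.52-fold in the mutant, and Jhbp14 rose at least 4.79-fold and fell by 1.13 on the log2 scale. Gdap1 fell by 1.52 on the log2 scale and CG10702 at least 4.58-fold in the mutant, while in the discs both lay under a log2 level of 4 in both groups. Of these 14 genes outside the V-ATPase, CG31098, CG3764, mol, GstT4, CG10702, CG8272 and CG3961 passed in both 6-array fits, and the replicate block ended the mutant call of Jhbp14 (adjusted p = 0.0584). Without single arrays CG11050 lost its disc call in 6 of 6 fits (adjusted p up to 0.143) and its mutant call in 4 (up to 0.0703). CG9757 and Jhbp14 lost the mutant call in 4 fits each (up to 0.109 and 0.0922). Sirup lost the disc call without control disc 1 (0.0505) and Gdap1 without labelled disc 3 (0.0564).

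Independent lists of these sizes, 543 genes higher in the discs and 550 lower in the mutant of 7809, would share 38.2 genes, and Fisher's exact test (one-sided) gave p = 0.000254, or 0.000507 adjusted over the 4 combinations of directions. Without the V-ATPase lists, 46 genes were shared against 36.2 (one-sided Fisher's exact test, p = 0.0521, adjusted 0.0754). Genes higher in both comparisons were more numerous, 78 against 44.1 (one-sided Fisher's exact test, adjusted p = 1.05e-06), while 36 were lower in both against 28.3 (adjusted p = 0.105) and 21 were lower in the discs and higher in the mutant against 32.6 (adjusted p = 0.992). Across all 7809 genes, which are not independent replicates, the changes in the 2 comparisons correlated at a Pearson r of 0.012 (Spearman rho 0.051), and across the 20 V-ATPase subunits at -0.62 (rho -0.42).

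**Figure D4:**
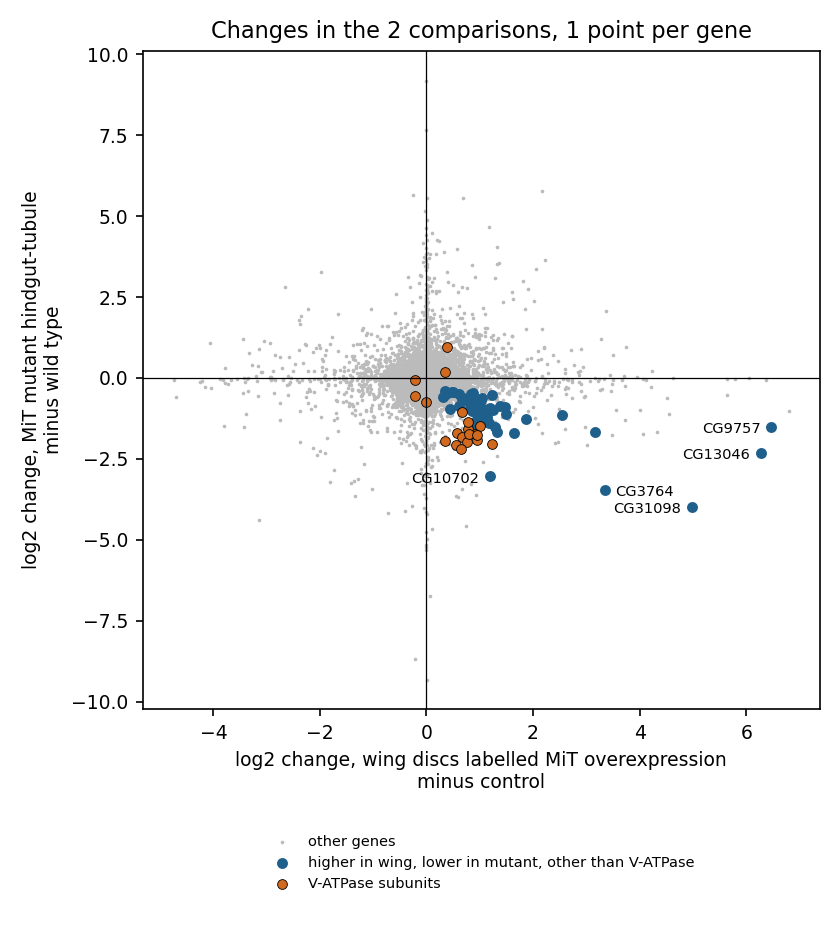
Log2 change in the wing discs (horizontal) against that in the mutant hindgut-tubule samples (vertical), 1 point per gene, with the V-ATPase subunits and the 46 other genes higher in the discs and lower in the mutant marked. Of 20 V-ATPase subunits 14 passed both tests, and CG31098 lies at 4.98 and -3.98.

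The shared count fell to 35 in the 6-array fits, 25 of which are among the 60, and all 14 V-ATPase subunits are among those 25. It came to 38 without labelled overexpressing disc 3, 94 without mutant array 2 and 154 without the number 2 arrays of both hindgut-tubule groups.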

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

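Leaving out the number 2 arrays was the only setting chosen after the results were seen. The direction of the V-ATPase lists and their camera call at the preset correlation held under every alternative fit in both tissues, and so did the fall of Mitf in the mutant, with adjusted p up to 0.0118. With an estimated correlation none of the V-ATPase lists passed camera (adjusted p = 0.42 and 0.237 in the discs, 0.249 and 0.067 in the mutant). Without the filter, which adds 10 dim V0 subunits, the V0 medians came to 0.0057 and -0.054, and the medians of all 33 subunits to 0.34 and -0.56. The 6 arrays of each tissue alone gave 1209 higher and 1395 lower probe sets in the wing discs, 182 and 167 in the hindgut-tubule samples and 35 shared genes. That fit changes both the spread and the residual degrees of freedom. On simulated data with 1500 changed probe sets and equal spread it made fewer calls than the 12-array fit in both tissues (1021 against 1106 and 992 against 1105). With the spread of each tissue it made more in the discs (1382 against 1124) and fewer in the hindgut-tubule samples (909 against 1336). In these simulations unequal spread thus moved the counts in the directions seen, and fewer degrees of freedom alone did not raise the disc counts. The counts in the real data moved by more than the simulated ones in both tissues, and what accounts for the rest was not tested. The shared count was not simulated. A threshold of at least 2-fold gave 343, 165, 270, 253 and 16, by its construction. The authors' deposited table, by its adjusted p, gave 39 shared genes. Its other counts, of 449, 305, 485 and 438, cover all probe sets of the arrays except controls. Among the probe sets tested here it called 703 in the discs and 862 in the mutant, against 1076 and 1328. Without the number 2 arrays of both hindgut-tubule groups, a setting added after seeing the data, the counts were 1288 higher, 984 lower and 154 shared. In that setting 3 further lists passed camera in place of 5. Oxidative phosphorylation kept its call, and the cell cycle (adjusted p = 0.0236) and heat shock (0.0232) lists gained one. The muscle, detoxification, ribosomal and antimicrobial lists lost theirs (0.170, 0.145, 0.170 and 0.170). The cause was not tested. Leaving out 1 array at a time gave 378 to 496 higher and 216 to 290 lower probe sets in the discs, 433 to 1106 higher and 446 to 733 lower in the mutant, and 38 to 94 shared genes. The shared genes without the V-ATPase were compared with chance by one-sided Fisher's exact tests. Their p ran from 1.80e-05 (no filter on dim probe sets) to 0.301 (arrays centred on their medians). In the main setting and in the 6-array fits it did not pass the threshold, so an excess over chance depended on the setting. Without the filter the number expected by chance was lower in every combination of directions, so that p is not directly comparable with the others.

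The lysosomal list in the mutant passed camera under the replicate block (median 0.20), renewed quantile normalization (0.22), centring (0.20) and without the number 2 arrays (0.24), all at the preset correlation (adjusted p = 0.958 with an estimated one in the main setting), and single left-out arrays moved its median between 0.13 and 0.29. Medians close to 0 changed sign: autophagy in the mutant to -0.016 after renewed normalization, -0.0045 after centring and -0.013 without the number 2 arrays, autophagy in the discs to 0.00026 after centring, and trafficking in the mutant to 0.0024 without the number 2 arrays; the cause was not tested. Over single left-out arrays the medians ran from -0.20 to 0.21 (autophagy, mutant), -0.042 to 0.015 (autophagy, discs), -0.21 to 0.015 (TORC1, mutant), -0.081 to 0.069 (trafficking, mutant) and -0.0093 to 0.13 (lysosomal, discs). None of these lists passed the test in the main setting.

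With the replicate number as a block the wing disc counts were 698 higher and 598 lower, the hindgut-tubule counts 786 and 851, and the shared genes 80. In the wing discs same-numbered arrays correlated at 0.33, -0.05 and -0.18, so the numbers there name arrays only. Of the genes named and called, the block ended 3 of 85 calls in the discs and 3 of 89 in the mutant, and apart from the lysosomal list it moved no main list across the threshold. The 6-array fit kept 84 of 85 named calls in the discs and 53 of 89 in the mutant, and 63 and 74 held in every fit that left out 1 array. Signal over background limits the many genes with a group mean under a log2 level of 4, which are 127 of 945 called genes in the discs and 128 of 1184 in the mutant.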

Other observations

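Single hormone and signalling genes moved in the discs labelled as overexpressing MiT. Of 18 genes of ecdysone response and staging, ftz-f1, a nuclear receptor of the prepupa, rose by 2.62 (SE 0.19, limma adjusted p = 1.40e-05), and ImpE2, ImpE1 and Eip78C fell, ImpE2 by 1.18 on the log2 scale (adjusted p = 0.000206); the list's median was -0.63 (camera adjusted p = 0.0832, and under 0.05 in 6 of 22 settings, among them the 6-array fit at 0.0146 and the replicate block at 0.0301, against 0.963 with an estimated correlation). Of 20 Notch pathway genes, E(spl)mgamma-HLH, E(spl)m4-BFM and vg fell and ct rose (camera adjusted p = 0.513). The mitotic activator stg rose by 0.81 in the discs (adjusted p = 0.013) and fell by 0.92 on the log2 scale in the mutant hindgut-tubule samples (adjusted p = 0.00564); the 6 hindgut-tubule arrays alone gave 0.092 there. Without single disc arrays ImpE1 lost its call in 6 of 6 fits, ct in 4, stg in 3 and E(spl)m4-BFM in 2, with adjusted p up to 0.153.

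In the mutant hindgut-tubule samples 3 of 15 genes of lipid storage and oxidation rose: Lip4, a lipase (1.10, adjusted p = 0.000921), SREBP (0.66) and the lipid droplet protein Lsd-2 (1.19). The 6-array fit called Lip4 alone of these. The cell death gene rpr (reaper) rose by 2.59 (SE 0.32, adjusted p = 0.000518). Among tubule markers, the pigment precursor transporter gene w (white) fell at least 9.42-fold (adjusted p = 0.000706) while SecCl, a chloride channel, rose by 0.89 (adjusted p = 0.000787). Among the 78 genes higher in both comparisons were EbpIII (2.02 in the discs and 2.39 in the mutant), Sp212 (2.23 in the discs and at least 12.2-fold in the mutant) and CG14879 (at least 1.95-fold and at least 28.8-fold), chosen after their values were seen.

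The tests of tissue share and of wing disc composition below were chosen after the result was seen, and the other tests were planned. The fall of V-ATPase subunits in the mutant may be a loss of expression that goes with the MiT genotype, or reflect what the samples held. A smaller share of tubule cells would lower tubule markers by as much, but the median of 21 tubule markers lay 1.78 above the V-ATPase median on the log2 scale, more than the SD of 1.05 over the markers. Compression of very bright signals would lower other bright genes, but lists matched on signal had a typical median of 0.061, and the lowest of 10000 such lists reached -0.36 against -1.72. Both tests, the second within this limit, argue against these explanations as the whole cause. A strain difference between mutant and wild type was not tested. It stays open for every hindgut-tubule change, the falls of w and Cyp12d1-d included, since genotype and strain cannot be separated in this design. The disc comparison has the same limit: by the labels every labelled disc carries the transgene and no control disc does, and a strain difference was not tested there.

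For the lower oxidative phosphorylation genes in the mutant the same pair of tests came out less clearly. Lists matched on signal in the same way had a typical median of 0.049 and the lowest reached -0.28, against -0.60. Within the same limit this argues against compression of bright signals. The tubule marker median lay 0.66 above the list's, within the SD of 1.05 over the markers, so by that rule a smaller share of tubule cells stays undecided. That SD is the scatter of single markers, not the uncertainty of the set. As a set the markers did not fall, with 13 positive and 8 negative. Between same-numbered arrays their mean differed by 0.065, 0.091 and -0.026, against -0.51, -0.60 and -0.64 for the list. These values argue against a smaller tubule share as the whole cause, although single markers scatter widely. The number 2 arrays of both genotypes read high for this list (0.39 in wild type and -0.22 in the mutant, minus the wild-type mean), and without both of them the median was -0.59.

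Of the hemocyte markers 5 of 9, and of the muscle markers 3 of 12, were higher in the discs labelled as overexpressing MiT. Both lists passed camera at the preset correlation, but not with an estimated one (adjusted p = 0.449 and 0.838). A smaller share of disc epithelium would raise every other tissue alike, but the hemocyte median exceeded the fat body median by 3.95 on the log2 scale, more than the spread of members (1.99) and of arrays (2.93). That gap rests on single discs: it was 2.29 against an array spread of 2.31 without labelled disc 3, and 3.84 against 4.13 without labelled disc 2. Markers of the salivary gland, also outside the disc, spread more widely, at -0.84, -4.42 and 5.26 on the control discs and -4.15, 2.65 and -1.39 on the labelled discs minus the control mean, a spread within groups that the genotype does not explain. Tracheal markers had a median of 0.65 with 3 of 4 positive and 1 past the limma test. Their list did not pass camera (adjusted p = 0.161), and its median went down to 0.27 in another setting. Neuron and glia markers had a median of 0.04 with 0 of 3 past the test. Lists this small do not decide whether the epithelial share was smaller. A smaller share of epithelium and a rise of hemocytes cannot be told apart here, because the markers of outside tissues differ so much between discs. Hml, Pxn, NimC1, He, srp, eater and crq were taken as 7 markers of plasmatocytes, the phagocytic hemocytes. Whether each of the 7 is confined to plasmatocytes was not checked. They had a median of 2.09 with 5 higher. These 5 are the members whose rise was seen first, so they do not test whether plasmatocytes were more numerous. In the same list PPO1 and PPO2, markers of crystal cells, had log2 changes of -0.11 and -0.19. More plasmatocytes stays open, and whether disc cells themselves express these genes more was not settled, because whole discs were measured.

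Other splits of the arrays were planned as a check on chance. For the wing discs the real split gave 1076 calls and the highest of the other 9 of 10 splits gave 5; for the hindgut-tubule samples the real split gave 1328 and the highest other 17, and the 3 others that part all same-numbered pairs gave at most 0. Each of these real splits is 1 of 10, and 10 splits cannot give a share under 0.1. For the 60 shared genes, 1 of 100 pairs of splits, the real one, reached that number in any combination of directions, and the highest other gave 1. By their call counts no other pair could have shared more than 16 genes, so this comparison decides nothing about chance.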
